A study of Mus musculus with 14 samples.

How the data were processed

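Total RNA from mouse corneal stroma and from cells grown out of it was measured on Affymetrix MG_U74Av2 arrays, 1 array per sample, 14 arrays in all. Per the labels, 3 arrays came from stroma of adult CD-1 mice aged 7 to 8 weeks, 2 from stroma at postnatal day 10 (P10), and 9 from adult stromal cells in culture. The 9 culture arrays were 3 keratocyte cultures in DMEM with 1% platelet-poor horse serum, 3 fibroblast cultures in 10% fetal bovine serum, and 3 myofibroblast cultures in 10% fetal bovine serum with 10 ng/ml TGF-beta1. RNA was isolated with TRIzol and 5 µg was labelled for each array.

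The deposited values are probe set signals in the unit intensity, on a linear scale with a floor at exactly 1, and the labels name Microarray Suite 5.0 with scaling to a target of 150. The 2% trimmed means of the deposited columns ran from 164.3 to 224.7, so the scaling of the values as deposited is not settled. The table holds no detection calls, and how signals below the floor were set is not given in the sources used here. Of the 12488 probe sets 876 held 2368 values at the floor, from 99 to 359 per array. No 2 columns were identical, and the correlation of log2 signals between arrays of a group ran from 0.911 to 0.987.

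For background, 19 control probe sets for transcripts that were not added gave a median signal of 42.19, a 95th percentile of 137.7 and a highest value of 256.8 over all arrays. A signal below 137.7 is therefore within the range of background. The median signal of an array ran from 102 to 135.7. Array signals carry no counts, so the number of arrays limits the precision.

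After 66 control probe sets were removed, 12422 remained. A probe set was kept when its mean signal was 50 or more in at least 1 of the 5 groups, which left 10370. Symbols came from the probe annotation. Of the 12422 probe sets 10833 had 1 symbol, 396 had several and 1193 had none, and the last 2 kinds entered the counts of probe sets but not the gene lists. The probe sets with 1 symbol that were kept (9173) stood for 7437 genes, and each gene was represented by its probe set with the highest mean log2 signal. Positions in the genome were not used here.

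Values of log2(signal + 16) were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 14 arrays in 1 fit (9 residual degrees of freedom) and an empirical Bayes variance with a trend on the mean signal. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 10370 probe sets of a comparison, and an adjusted p below 0.05 was called. A fold against a group at the floor depends on the added 16. Means and SDs are those of the deposited signals. The comparisons were adult minus P10 stroma, keratocyte culture minus adult stroma, the 3 differences between cultures, and the other 2 cultures minus adult stroma, for which counts and gene lists are given. The last difference between cultures, myofibroblast minus keratocyte, is the sum of the other 2.

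Gene lists, 32 in number, were written from general knowledge of the cornea, of matrix and of cell types, and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether the genes of a list moved more than other genes did. Members past the threshold were counted over all probe sets and again with p adjusted over the list alone. Each list was tested again with a correlation estimated from the data and with fry, which asks whether the genes of a list moved one way on balance. Named genes followed a rule: the 10 largest rises and falls whose arrays did not overlap, up to 4 members of each list that was called or had 4 or more members past the threshold, and 15 marker genes of keratocytes, myofibroblasts, epithelium and inflammation, of which C3 was not measured. Groups, comparisons, lists, this rule and the alternatives were chosen before the data were examined, except where stated.

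Simulated data were used to check the fit. With 200 of 10370 probe sets changed, 37% to 65% of those changed by 1 on the log2 scale were recovered over the 7 comparisons, and 89% to 98% of those changed by 2, with 4 to 16 false calls. These made up 2.5% to 9.41% of the calls of a comparison. The simulated arrays were independent and each probe set had the same SD in every group. Unequal spread between groups and paired arrays were therefore not checked.

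The alternatives were another added constant (1 or 64), no filter or a filter at 100, quantile normalization, centring of each array on its median, a fit with only the 2 groups compared, the replicate number as a block, other forms of the variance estimate, array quality weights, the 3'/5' ratio of Gapdh as a covariate, stricter thresholds, the median over the probe sets of a gene, and leaving out each array. Whether replicate numbers pair arrays was read from the correlation of their deviations from the group means, over 0.1 for every number. Only myofibroblast and fibroblast cultures met this (0.62, 0.68 and 0.53 for numbers 1 to 3), and each of their 6 arrays went best with its own number. The pairing thus comes from the data, since the labels do not say what a number marks. The correlation of each culture array with the mean of the adult arrays, over probe sets, was compared between cultures by exact permutation tests. The labels do not say whether replicates were separate animals or separate cultures, so p-values measure only the spread between these samples.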

Results

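Gene expression was measured in the stroma of the mouse cornea, the collagen-rich layer kept by keratocytes, at P10 and in the adult, and in adult stromal cells cultured in 3 ways that are named after the cell type each favours. There were 3 arrays per group, except 2 for P10. The 3'/5' signal ratio of Gapdh, which rises when RNA is degraded, was 1.36 ± 0.665 (SD, n = 3) in adult stroma, with 2.121 on adult replicate 1, and 0.916 ± 0.0287 (SD, n = 2) in P10 stroma. It was 0.847 ± 0.00459, 0.816 ± 0.0369 and 0.779 ± 0.035 (SD, n = 3 each) in keratocyte, fibroblast and myofibroblast cultures. The 3'/5' ratio of Actb was 2.438 ± 1.404 in adult and 1.453 ± 0.0185 in P10 stroma. In the cultures, in the same order, it was 1.123 ± 0.0619, 1.135 ± 0.0657 and 1.103 ± 0.0472. Every tissue array (1.44 or more) had a higher Actb ratio than every culture array (1.196 or less). The signal of added control transcripts was 1499 ± 225 in adult and 941 ± 170.5 in P10 stroma. In keratocyte, fibroblast and myofibroblast cultures it was 525.8 ± 119, 664.7 ± 113.1 and 603.8 ± 193.8. Every tissue array (820.4 or more) lay above every culture array (806.7 or less), and every adult array above every P10 array. What this difference does to the comparisons was not tested. All values are signals given as mean ± SD, with the n of these groups. No log2 difference of a gene is printed where a group mean was below 137.7, within background. In each named gene past the threshold every array of 1 group lay above every array of the other, which for the largest changes was a condition of naming.

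**Figure D1:**
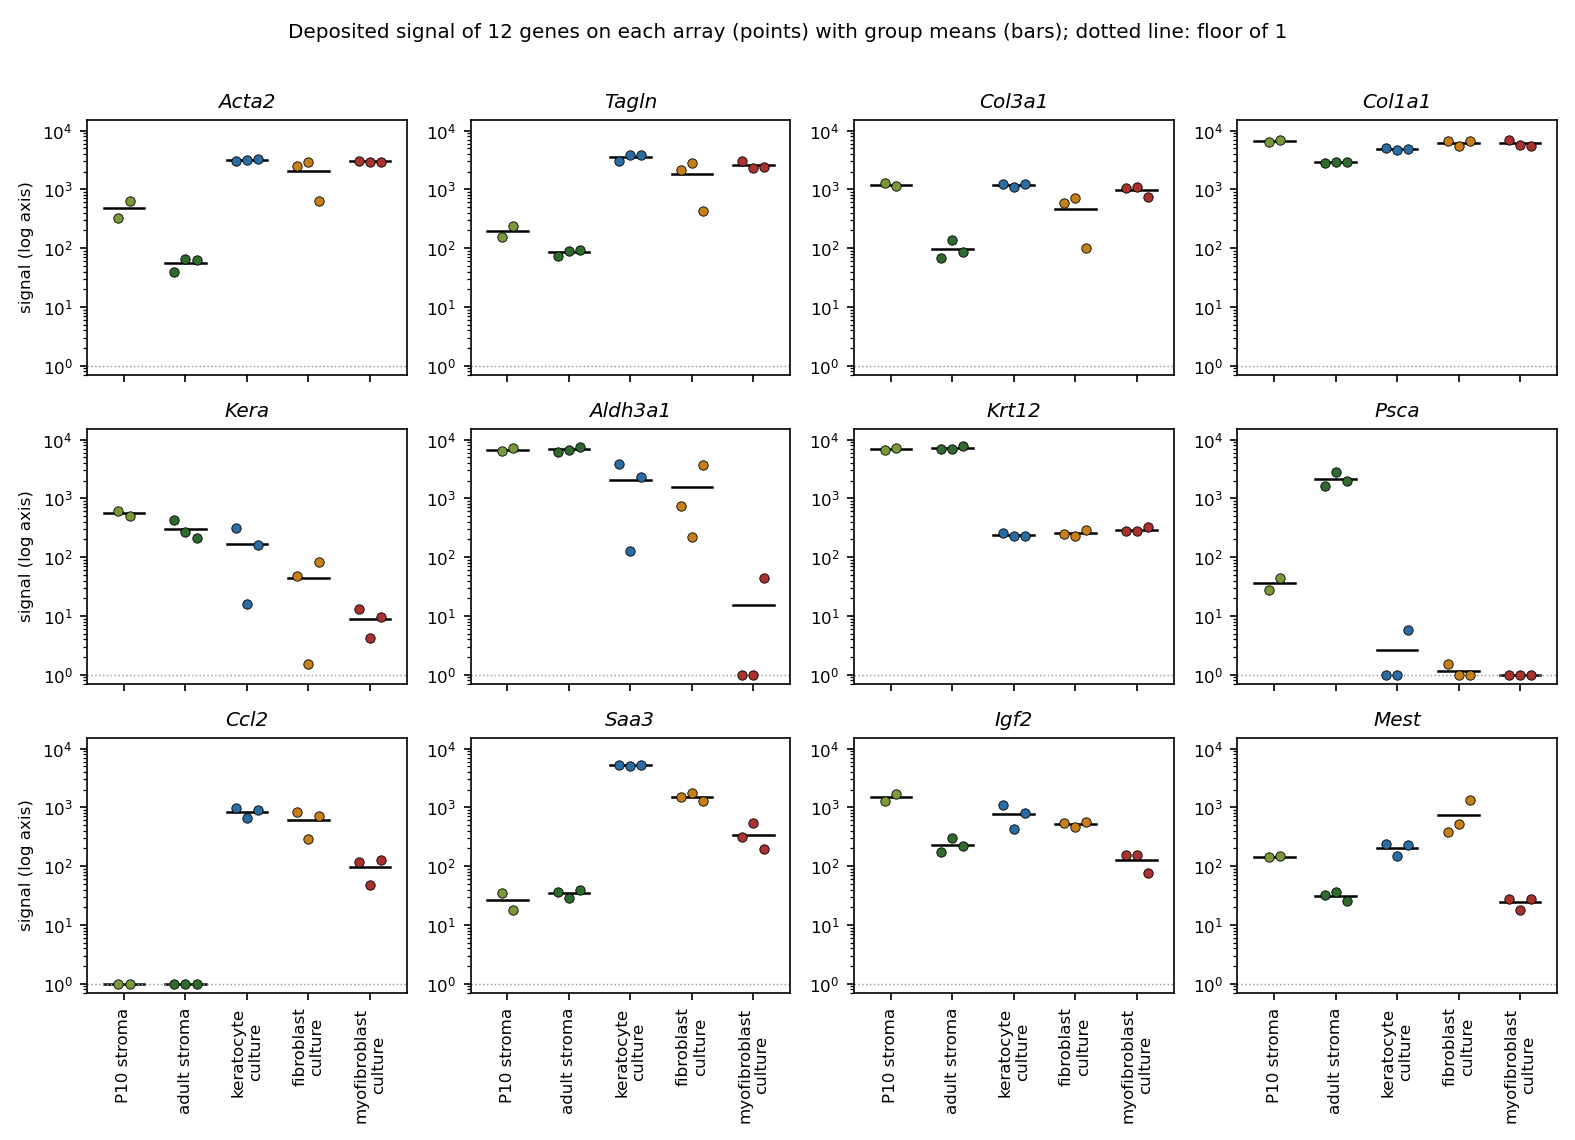
Deposited signal (log axis) of 12 genes on each array (points), with the group mean as a bar and the floor of 1 as a dotted line, for 2 P10, 3 adult and 3 arrays of each culture. Acta2 was at 3193 ± 142 in keratocyte culture and 56 ± 14.3 in adult stroma, and fibroblast replicate 3 lay below the other fibroblast arrays for Acta2, Tagln and Col3a1.

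Adult stroma was compared with P10 stroma, which asks what changes between the days before the eyes open and adulthood. Fibrillar collagen genes fell to adulthood. The median levels of lens and retina markers, given below, were also lower in the adult, so a different make-up of the dissected tissue is not excluded. Col1a1, a chain of the main collagen of the stroma, was at 6640 ± 404 at P10 and 2882 ± 58.8 in the adult, a change of -1.20 on the log2 scale (adjusted p = 0.000195). Col3a1, a collagen of growing and healing tissue, fell from 1205 ± 111 to 98.2 ± 36.9 (adjusted p = 0.00247). Col5a1 and Col5a2, whose chains set the width of collagen fibrils, fell from 1095 ± 206 to 214 ± 74.2 and from 2281 ± 203 to 499 ± 151. Of 11 fibrillar and fibril-associated collagens 7 fell, 0 rose and 4 did not pass, and 8 fell when adjusted over the list alone. Of 17 basement membrane genes 8 fell and 9 did not pass, and 12 fell when adjusted over the list alone, among them Col4a1, from 1297 ± 83.2 to 279 ± 16.8, and Col4a2, from 445 ± 11.3 to 139 ± 14.

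Of the genes that mature collagen few passed. Lox, which cross-links collagen, fell from 222 ± 26 to 37.8 ± 23.2 (adjusted p = 0.000282), and Serpinh1, a collagen chaperone, was at 1527 ± 34.4 and 500 ± 184 (adjusted p = 0.00119, 0.0565 with only the 2 groups in the fit). Of 11 genes for collagen processing and cross-linking 2 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone. Among 8 small leucine-rich proteoglycans, which space the fibrils, 2 fell and 4 did so adjusted over the list alone. Bgn fell from 1948 ± 46.9 to 814 ± 198 (adjusted p = 0.000628). Fmod was at 691 ± 140 and 229 ± 44.2 (adjusted p = 0.00945, 0.158 without P10 replicate 1). The keratocyte proteoglycans Kera and Lum did not pass, at 557 ± 74.6 and 2368 ± 393 at P10 and 303 ± 112 and 1178 ± 370 in the adult (adjusted p = 0.691 and 0.194).

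Some imprinted growth genes were lower in the adult. The growth factor gene Igf2 fell from 1495 ± 276 to 230.4 ± 63.1 (adjusted p = 0.000775), and Cdkn1c, an imprinted inhibitor of cell division, fell from 547 ± 21.1 to 66.9 ± 22.6 (adjusted p = 0.000263). Of 16 imprinted growth genes 7 fell, and 10 fell adjusted over the list alone, but the call of the list was lost with an estimated correlation. In the insulin-like growth factor system 3 of 12 genes fell, and 5 did adjusted over the list alone, with Htra1, a protease that cleaves binding proteins of these factors, falling from 945 ± 7.49 to 362 ± 47.5. Of 22 contractile cytoskeleton genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.053, 0.0129 after quantile normalization and 0.0297 after centring). Tpm1, a tropomyosin of stress fibres, fell from 642 ± 95.2 to 219 ± 28 and Actn1, an alpha-actinin, from 239.7 ± 15 to 96.7 ± 4.95, while Acta2, the smooth muscle actin that marks myofibroblasts, was at 475 ± 211 and 56 ± 14.3 (adjusted p = 0.00473, 0.109 without P10 replicate 2). Fn1, the fibronectin gene, was at 2944 ± 12.4 and 1278 ± 337 (adjusted p = 0.00112, 0.0556 with only the 2 groups in the fit).

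The largest rise was that of Psca, a surface protein of epithelia, from 35.7 ± 11.2 to 2143 ± 622 (adjusted p = 3.43e-08). Tgm2, a transglutaminase that cross-links matrix proteins, rose from 118 ± 0.259 to 1235 ± 522, and Asprv1, a protease of stratified epithelium, from 678 ± 348 to 2732 ± 72.2. The neuropeptide gene Npy rose from 164 ± 36.9 to 758 ± 208. Psmb8, a subunit of the immunoproteasome, rose from 113 ± 8.03 to 399 ± 119 (adjusted p = 0.000981), and 3 of 23 interferon-stimulated genes rose, 6 when adjusted over the list alone. Krt12, the keratin of corneal epithelium, was at 7148 ± 507 in adult and 6891 ± 476 in P10 stroma (adjusted p = 0.936), and Aldh3a1, the corneal crystallin enzyme, was at 6771 ± 631 and 6726 ± 474 (adjusted p = 1).

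Lists of lens and retina markers did not pass (adjusted p = 0.138 and 0.256), with 1 of 9 and 1 of 11 genes falling and median log2 differences of -0.41 and -0.33 per gene. The median log2 level of the lens list was still higher at P10, at 9.68 ± 0.04 against 8.40 ± 0.16 in the adult. That of the retina list was 8.50 ± 0.41 against 7.34 ± 0.58. A different share of neighbouring tissue at the ages compared is therefore not excluded. Pigment cell genes were lower in the adult but varied between the P10 arrays. Of 7 melanocyte and pigment cell markers 3 fell, and 4 did adjusted over the list alone. Pmel, a structural protein of pigment granules, was at 170.4 ± 33.6 in the adult and 1378 ± 1196 at P10, with 532.6 and 2224 on the P10 arrays (adjusted p = 0.00159, 0.0708 with only the 2 groups in the fit). Of 27 corneal epithelium markers 5 fell (8 fell and 2 rose adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.822), with a median log2 difference above 0 (0.02), a mean below it (-0.29) and a test that pointed down.

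Across all probe sets 385 differed, 47 higher and 338 lower in the adult (319 by 2-fold or more, 35 higher and 284 lower). The split was 107 and 313 after quantile normalization and 84 and 255 after centring, since the median log2 difference of all probe sets was -0.12 as deposited and 0.047 after centring. By camera 11 lists were called. Collagens (adjusted p = 6.66e-09), basement membrane (4.51e-10) and the insulin-like growth factor system (0.000342) also passed with an estimated correlation (0.00778, 0.0173 and 0.0241). Imprinted growth genes (4.2e-08, adjusted p = 0.132 with an estimated correlation), interferon-stimulated genes (1.56e-09, adjusted p = 0.0761 with an estimated correlation), pigment cell markers (0.000319, adjusted p = 0.132 with an estimated correlation), proteoglycans (0.00169, adjusted p = 0.132 with an estimated correlation) and collagen processing (0.00303, adjusted p = 0.118 with an estimated correlation) did not. Lower TGF-beta responsive genes (0.00303, with 5 of 25 lower; 0.0561 without adult replicate 3; adjusted p = 0.486 with an estimated correlation) and higher cholesterol synthesis (0.00146, with 0 of 14 past the threshold; 0.0539 without adult replicate 2; adjusted p = 0.44 with an estimated correlation) rested on single arrays. Higher antioxidant genes (0.0173; adjusted p = 0.555 with an estimated correlation) ended without adult replicate 2 (0.0887), without P10 replicate 2 (0.0926), after quantile normalization (0.097) and after centring (0.0614).

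The number of probe sets depended on single arrays: 220 without adult replicate 1, whose 3'/5' ratios stood apart, an alternative planned but singled out after the data were seen, 117 without P10 replicate 1 and 134 without P10 replicate 2. Leaving out a P10 array leaves 1, which is then assumed to vary like the other groups. With only the 2 groups in the fit 225 differed, 198 with the Gapdh ratio as a covariate and 2335 with array quality weights.

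Keratocyte culture was compared with adult stroma, which asks what cells taken from the stroma and kept in low serum retain of the tissue. Markers of the quiescent keratocyte parted. Dcn, the decorin gene, rose from 3491 ± 292 to 5285 ± 428 (log2 0.60, adjusted p = 0.00113) and Ogn, the osteoglycin gene, from 193 ± 23.9 to 1466 ± 1002 (adjusted p = 0.00371). Tkt, a transketolase abundant in the cornea, fell from 5006 ± 188 to 1062 ± 450 (adjusted p = 3.92e-06). Kera was at 303 ± 112 in tissue and 165 ± 150 in culture (adjusted p = 0.182, 0.0153 with array quality weights). Aldh3a1 was at 6771 ± 631 and 2076 ± 1839 (adjusted p = 0.0732, 0.0305 without keratocyte replicate 1 and 0.0399 after centring), and Lum at 1178 ± 370 and 2309 ± 1086 (adjusted p = 0.0681, 0.00341 without keratocyte replicate 2 and 0.049 without adult replicate 1). Tkt and Aldh3a1 are also made by corneal epithelium, whose markers fell with them (23 of 27, median log2 difference -3.47). Both Kera and Aldh3a1 were low on keratocyte replicate 2, at 15.72 and 124.9, against 315.1 and 3778 on replicate 1 and 164 and 2327 on replicate 3. Of 10 keratocyte markers 5 rose and 1 fell, 6 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.593).

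Contractile genes rose, including the marker of myofibroblasts. Acta2 went from 56 ± 14.3 to 3193 ± 142 (adjusted p = 2.19e-07) and Tagln, the transgelin gene of smooth muscle, from 85.7 ± 10.7 to 3527 ± 466 (adjusted p = 1.65e-06). Actn1 rose from 96.7 ± 4.95 to 2663 ± 221, Tpm1 from 219 ± 28 to 3060 ± 163 and Myl9, a myosin light chain of contractile cells, from 97.2 ± 8.68 to 1012 ± 114. Of 22 contractile cytoskeleton genes 14 rose, 4 fell and 4 did not pass, the same adjusted over the list alone. TGF-beta responsive genes went with them, 20 of 25 rising and 1 falling (20 and 2 adjusted over the list alone). Among these Ccn2, a growth factor of scars, rose from 56.2 ± 46.5 to 3730 ± 173 and Id3, an inhibitor of differentiation factors, from 121 ± 21.6 to 892 ± 67.4. In contrast Tgfbi, the TGF-beta induced matrix protein abundant in the cornea, fell from 2742 ± 97.7 to 307 ± 108 (log2 -3.15, adjusted p = 5.2e-06). Most corneal epithelium markers fell in the same comparison, so a different share of epithelial cells is not excluded for Tgfbi.

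Matrix genes rose, in a comparison where epithelial markers fell (23 of 27), so that a different share of stromal cells is not excluded for modest rises such as that of Col1a1. Lox went from 37.8 ± 23.2 to 2796 ± 86.7, Fn1 from 1278 ± 337 to 4358 ± 235, Col3a1 from 98.2 ± 36.9 to 1185 ± 87.9, and Col1a1 from 2882 ± 58.8 to 4870 ± 230. Among 11 collagens 7 rose and 1 fell (7 and 2 adjusted over the list alone), among 11 collagen processing genes 8 rose and 1 fell (9 and 1), and among 17 basement membrane genes 11 rose and 1 fell (12 and 1). Lama3, a laminin chain of epithelial basement membrane, was the one that fell, from 447 ± 152 to 18.1 ± 2.35. Bgn rose from 814 ± 198 to 4777 ± 378 and Fmod from 229 ± 44.2 to 2557 ± 198, with 4 of 8 proteoglycans rising (6 adjusted over the list alone). Of 19 matrix proteases and inhibitors 13 rose and 0 fell (14 adjusted over the list alone), among them Timp1, which inhibits matrix metalloproteinases, from 127 ± 23.2 to 5074 ± 330.3, and Mmp3, the stromelysin gene, from 103 ± 42.3 to 2611 ± 256. Timp2 was at the floor of 1 on all 3 adult arrays and at 1529 ± 182 in culture.

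Chemokines and some genes of the acute phase rose. Saa3, an acute phase protein, rose from 34.7 ± 5.41 to 5205 ± 133 (adjusted p = 3.23e-10), and Serpina3n, a protease inhibitor of the acute phase, from 43.4 ± 27.4 to 3368 ± 409. Ccl2, a chemokine that draws monocytes, was at the floor on all adult arrays and at 843 ± 158 in culture, and Cxcl5, a chemokine for neutrophils, was at 1.93 ± 1.07 and 1038 ± 241. Of 24 chemokines and cytokines 14 rose and 2 fell, 16 and 2 adjusted over the list alone. The list of complement and host defence genes did not pass, with 7 of 14 higher and 2 lower (adjusted p = 0.1). Ptx3, a soluble pattern receptor, rose from 39.4 ± 25.7 to 966 ± 126. Interferon-stimulated genes went the other way, 12 of 23 falling and 2 rising (the same adjusted over the list alone) in a comparison where 23 of 27 epithelial markers fell, with Psmb8 falling from 399 ± 119 to 83.3 ± 13.1 and Irf1, an interferon regulatory factor, from 456 ± 129 to 192 ± 15.7, while B2m, the light chain of class I molecules, rose from 560.3 ± 230 to 2455 ± 260.

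Markers of macrophages were higher in culture, 12 of 24 rising and 1 falling (13 and 2 adjusted over the list alone). C1qa and C1qc, complement chains made by macrophages, rose from 76.2 ± 20.6 to 317 ± 16.4 and from 112 ± 13.8 to 355 ± 16.5, and Lyz2, the lysozyme of myeloid cells, from 4.85 ± 6.68 to 1130 ± 262. Tyrobp, an adaptor of myeloid receptors, rose from 11.8 ± 2.64 to 199 ± 53.4. These levels of C1qa, C1qc and Tyrobp in tissue are within background.

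Epithelial genes were among the largest falls. Krt12 went from 7148 ± 507 to 238 ± 13.2 (log2 -4.82, adjusted p = 6.54e-12). Col17a1, a collagen of hemidesmosomes, was at 2459 ± 469 in tissue and at the floor on all keratocyte arrays, as was Itgb4, its integrin partner, from 1420 ± 282. Krt14, a keratin of basal cells, fell from 1166 ± 235 to 1.08 ± 0.142, Dsp, the desmoplakin gene, from 2834 ± 410 to 32.7 ± 1.11, and Psca from 2143 ± 622 to 2.61 ± 2.79. Of 27 corneal epithelium markers 23 fell, 1 rose and 3 did not pass, the same adjusted over the list alone, with a median log2 difference of -3.47, a size that depends on the added 16 where levels in culture were within background.

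Genes of neighbouring eye tissues fell as well. Of 9 lens crystallins 4 fell and 1 rose, with Cryaa, the alpha-A crystallin, at 2611 ± 698 in tissue and 102 ± 3.6 in culture and Cryba1 at 1760 ± 401 and 23.1 ± 7.8. Of 11 retina and photoreceptor markers 8 fell, among them Sag, the arrestin of rods, at 1159 ± 1043 and 7.07 ± 3.37. The median log2 level of the retina list was 7.34 ± 0.58 in adult and 8.50 ± 0.41 in P10 stroma and 5.34 ± 0.18 in keratocyte culture. Among 13 blood and haemoglobin genes 4 fell and 1 rose, with Hba-a1, an alpha globin, falling from 797 ± 223 to 166 ± 1.65.

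Glycolysis, protein folding and growth factor genes rose, while the lists of cholesterol synthesis (0 of 14, adjusted p = 0.355), oxidative phosphorylation (4 higher and 1 lower of 24, 0.921) and antioxidant genes (10 higher and 5 lower of 32, 0.503) did not pass. Of 16 glycolysis genes 10 rose and 0 fell, with Pgk1, phosphoglycerate kinase, rising from 549 ± 59.2 to 2089 ± 102 and Pgam1, phosphoglycerate mutase, from 372 ± 84.2 to 1318 ± 41.9. Of 17 genes for folding and stress in the endoplasmic reticulum 13 rose (15 adjusted over the list alone), with Pdia6, a disulfide isomerase, rising from 118 ± 47.3 to 766 ± 102 and Atf4, a stress transcription factor, from 491 ± 111 to 1134 ± 99.2. Of 16 imprinted growth genes 11 rose (12 adjusted over the list alone), among them Mest, from 31.7 ± 5.19 to 207 ± 49.7, and Gnas, a G protein subunit, from 2451 ± 274 to 4390 ± 112. Of 12 genes of the insulin-like growth factor system 7 rose and 1 fell (9 and 1 adjusted over the list alone), with Igfbp2, a binding protein, rising from 1514 ± 268 to 5313 ± 195. The cell cycle list did not pass (adjusted p = 0.133), with 11 of 37 genes rising and 2 falling (12 and 2 adjusted over the list alone). Cdk1, the mitotic kinase, rose from 177 ± 20.6 to 380.2 ± 31.

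Across all probe sets 3221 differed, 2262 higher and 959 lower in culture (1771 by 2-fold or more, 1287 and 484), and 1884 and 1651 after quantile normalization or 1796 and 1643 after centring, which took the median log2 difference of all probe sets from 0.12 to -0.064. With array quality weights 6366 differed. Camera called 18 lists, and the fall of corneal epithelium markers (adjusted p = 6.37e-28) also passed with an estimated correlation (0.00522). None of the rises did. They were TGF-beta responsive genes (2.24e-07, adjusted p = 0.125 with an estimated correlation), proteases (2.81e-05, adjusted p = 0.0792 with an estimated correlation), collagen processing (6.16e-05, adjusted p = 0.0638 with an estimated correlation), chemokines (9.23e-05, adjusted p = 0.125 with an estimated correlation), endoplasmic reticulum (0.000128, adjusted p = 0.157 with an estimated correlation), imprinted genes (0.000302, adjusted p = 0.245 with an estimated correlation), glycolysis (0.000733, adjusted p = 0.125 with an estimated correlation), basement membrane (0.00126, adjusted p = 0.125 with an estimated correlation), contractile genes (0.00141, adjusted p = 0.272 with an estimated correlation) and the insulin-like growth factor system (0.00289, adjusted p = 0.0792 with an estimated correlation). The falls of the retina (1.73e-06, adjusted p = 0.125 with an estimated correlation), interferon (9.58e-05, adjusted p = 0.157 with an estimated correlation) and lens lists (0.000129, adjusted p = 0.0948 with an estimated correlation) did not either. The lists of macrophage markers (0.0136, adjusted p = 0.382 with an estimated correlation) and collagens (0.0257, adjusted p = 0.125 with an estimated correlation) were each at 0.0518 without adult replicate 2. Proteoglycans (0.0382, adjusted p = 0.245 with an estimated correlation) were at 0.0662 without adult replicate 3. Blood genes (0.048, adjusted p = 0.275 with an estimated correlation) ended without adult replicate 2 (0.0822), adult replicate 3 (0.0856), keratocyte replicate 1 (0.0633) or keratocyte replicate 3 (0.0539), and after quantile normalization (0.0745) or centring (0.0586).

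**Figure D2:**
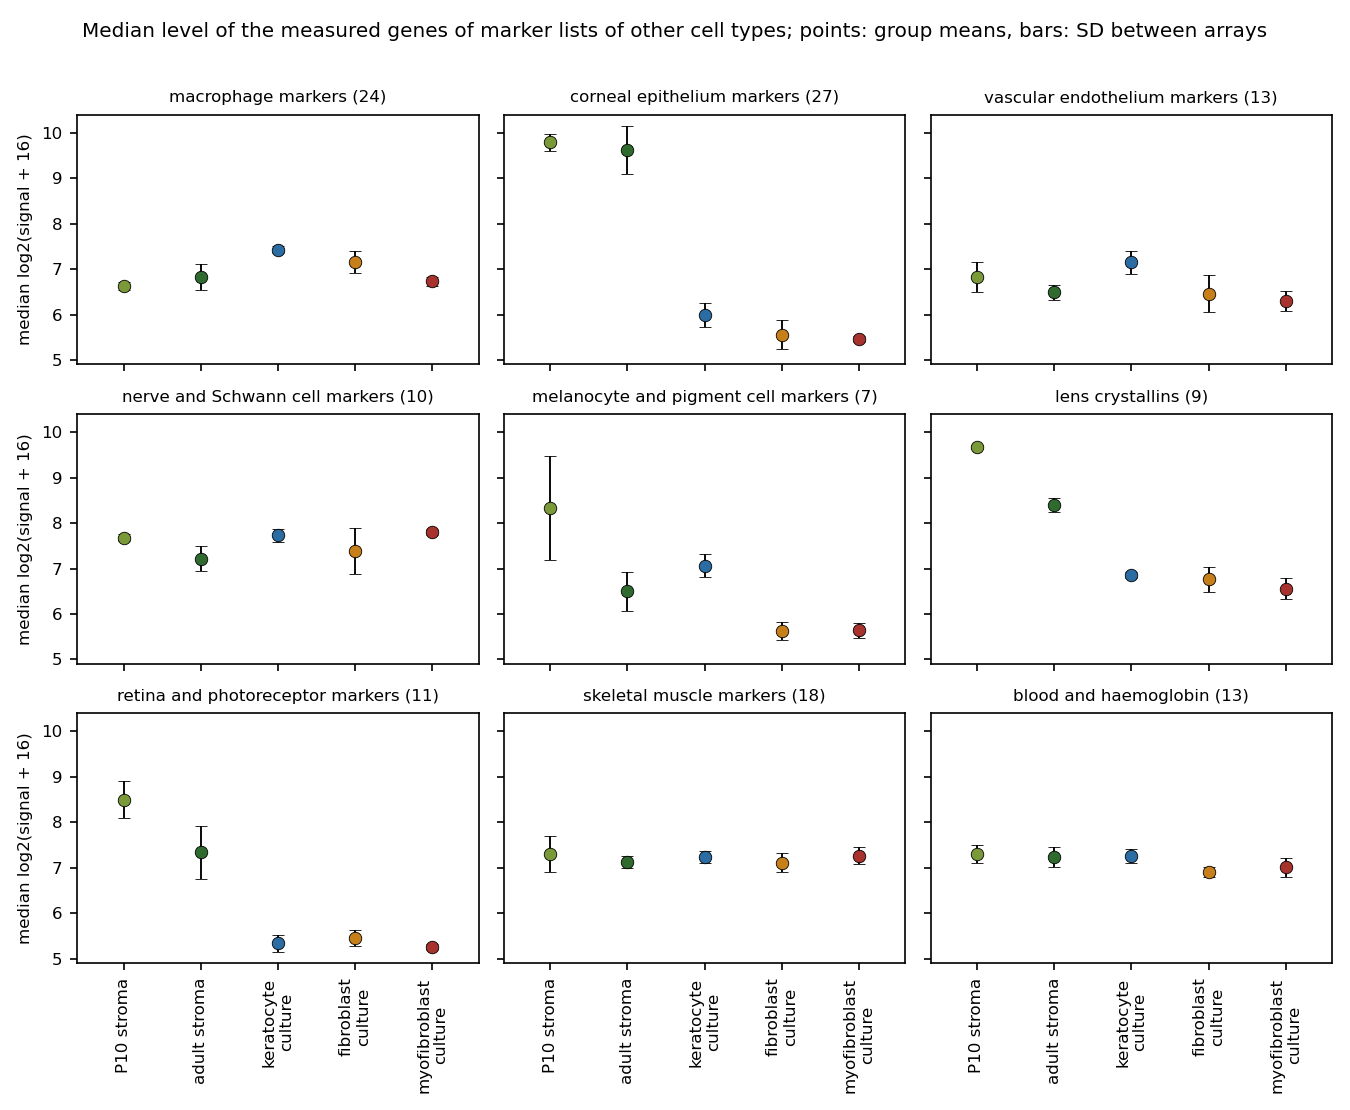
Median level, as log2(signal + 16), of the measured genes of 9 marker lists of other cell types, with points for group means and bars for the SD between arrays (2 for P10 stroma, 3 for the others). Corneal epithelium markers were at 9.79 ± 0.19 in P10 and 9.62 ± 0.53 in adult stroma and at 5.99 ± 0.26 in keratocyte culture.

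Fibroblast culture was compared with keratocyte culture, which sets 10% fetal bovine serum against 1% horse serum, so that kind and amount of serum changed together. Most pigment cell markers and some macrophage markers were lower in fibroblast culture. Dct, an enzyme of melanin synthesis, fell from 1200 ± 92.4 to 329 ± 79.2 (log2 -1.85, adjusted p = 0.00235) and Kit, a receptor of melanocytes, from 119 ± 23.2 to 32.1 ± 7.73, where both levels of Kit are within background. Of 7 pigment cell markers 5 fell, and 7 did adjusted over the list alone. C1qa fell from 317 ± 16.4 to 122 ± 24.4 (adjusted p = 0.00422) and C1qc from 355 ± 16.5 to 160.2 ± 11 (adjusted p = 0.00195). Of 24 macrophage markers 7 fell and 0 rose, and 8 fell adjusted over the list alone. The call of the macrophage list was lost with an estimated correlation.

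Lcn2, a lipocalin that binds bacterial iron carriers, fell from 905 ± 157 to 109 ± 23.6 (adjusted p = 0.00185), and Angptl4, a secreted inhibitor of lipoprotein lipase, from 1090 ± 155 to 228 ± 107. The list of complement and host defence genes did not pass, with 2 of 14 lower (adjusted p = 0.439). Aldoc, an aldolase, fell from 362 ± 15.4 to 85 ± 14.9 (adjusted p = 5.75e-05). Of 16 glycolysis genes 3 fell (6 and 1 higher adjusted over the list alone). Of 14 cholesterol synthesis genes 3 fell and 7 did adjusted over the list alone, with Idi1, an isomerase of the pathway, at 364 ± 42.3 and 137 ± 19.6 (adjusted p = 0.0214, but 0.0634 and 0.0675 without fibroblast replicates 1 and 3 and 0.111 and 0.127 without keratocyte replicates 1 and 3). Ptgds, the prostaglandin D synthase of keratocytes, was at 1140 ± 74.8 and 313 ± 118 (adjusted p = 0.00675, 0.0557 without keratocyte replicate 3, 0.0676 with only the 2 groups in the fit).

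Few genes rose in fibroblast culture. Penk, the proenkephalin gene, rose from 519.9 ± 41.8 to 1499 ± 295 (log2 1.49, adjusted p = 0.00195). Thbs2, a matrix thrombospondin, was at 761 ± 257 and 2660 ± 920 (adjusted p = 0.0102, 0.0577 without keratocyte replicate 3, 0.116 with only the 2 groups in the fit). Cell cycle genes were higher as a list, with 2 of 37 past the threshold and 7 adjusted over the list alone, and a median log2 difference of 0.15 (adjusted p = 4.2e-08, adjusted p = 0.435 with an estimated correlation).

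Of the markers that name the cultures Ptgds passed, as given above, and the following did not. Acta2 was at 3193 ± 142 in keratocyte and 2046 ± 1236 in fibroblast culture (adjusted p = 0.579), and Tagln at 3527 ± 466 and 1803 ± 1236 (adjusted p = 0.343), both being lowest on fibroblast replicate 3, at 638.4 and 428.2. Aldh3a1 was at 2076 ± 1839 and 1565 ± 1886 (adjusted p = 0.97) and highest among the fibroblast arrays on that same replicate, at 3721. Kera was at 165 ± 150 and 44.7 ± 41.5 (adjusted p = 0.66), Lum at 2309 ± 1086 and 2262 ± 540 (adjusted p = 0.976), Dcn at 5285 ± 428 and 5136 ± 438 (adjusted p = 0.957) and Fn1 at 4358 ± 235 and 5115 ± 416 (adjusted p = 0.769).

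Across all probe sets 142 differed, 20 higher and 122 lower in fibroblast culture (123 by 2-fold or more, 14 and 109), and 39 and 110 after quantile normalization or 46 and 107 after centring, which took the median log2 difference of all probe sets from -0.0927 to 0.024. Of 9 lists called, the fall of pigment cell markers (adjusted p = 2.15e-12) also passed with an estimated correlation (0.0439). The rise of cell cycle genes and the falls of cholesterol synthesis (2.48e-06, adjusted p = 0.398 with an estimated correlation), macrophage markers (7.84e-06, adjusted p = 0.398 with an estimated correlation) and glycolysis (0.000894, adjusted p = 0.398 with an estimated correlation) did not. The rise of endoplasmic reticulum genes (0.0103, 0 of 17 past the threshold; adjusted p = 0.483 with an estimated correlation) ended without fibroblast replicate 1 (0.0579), fibroblast replicate 3 (0.0697) or keratocyte replicate 2 (0.084). The fall of vascular endothelium markers (0.0298, 2 of 13 lower; adjusted p = 0.435 with an estimated correlation) ended without fibroblast replicate 1 (0.0814) or keratocyte replicate 2 (0.0729). That of keratocyte markers (0.0332, 1 of 10 lower, 2 adjusted over the list alone; adjusted p = 0.483 with an estimated correlation) ended without fibroblast replicates 1 (0.0939) or 2 (0.101) or keratocyte replicates 1 (0.229) or 3 (0.0662). The fall of basement membrane genes (0.038, 2 of 17 lower; adjusted p = 0.483 with an estimated correlation) ended without fibroblast replicate 1 (0.158), keratocyte replicate 1 (0.0763) or keratocyte replicate 3 (0.0509).

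The number of probe sets was 59 without fibroblast replicate 3, 36 without keratocyte replicate 1 and 20 without keratocyte replicate 3. It was 46 with only the 2 groups in the fit, 83 with 1 added to the signals in place of 16 and 360 with array quality weights.

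Myofibroblast culture was compared with fibroblast culture, which asks what TGF-beta1 adds in the presence of serum. Among the genes that rose were 6 of different functions. Cdkn2b, an inhibitor of cyclin-dependent kinases induced by TGF-beta, rose from 36.2 ± 7.82 to 238 ± 65.2 (adjusted p = 0.00046). Crabp2, a carrier of retinoic acid, rose from 39.4 ± 29.3 to 379.8 ± 6.67 (adjusted p = 0.000345) and Ccn4, a matricellular protein, from 289 ± 74.5 to 1279 ± 368. Rasl11b, a small GTPase, rose from 64.2 ± 17 to 387 ± 87.8, Anxa8, an annexin, from 93.8 ± 20.5 to 443 ± 69.5, and Tfpi2, an inhibitor of serine proteases, from 28.7 ± 13 to 203 ± 43.7. Of 25 TGF-beta responsive genes 2 rose and 1 fell, 9 and 5 adjusted over the list alone.

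Several inflammatory genes fell. Ccl2 went from 613 ± 286 to 97.2 ± 42.9 (adjusted p = 0.00268), Cxcl5 from 1051 ± 677 to 68.5 ± 51.1 and Saa3 from 1498 ± 228 to 345 ± 173. Ptx3 fell from 931 ± 209 to 89.4 ± 36.6 (adjusted p = 0.000251) and Serping1, the inhibitor of the first complement component, from 1993 ± 565 to 319 ± 74.4 (adjusted p = 0.000251). Of 14 complement and host defence genes 4 fell and 0 rose, 6 adjusted over the list alone. Of 24 chemokines and cytokines 5 fell, but the list did not pass (adjusted p = 0.146, 0.0324 without myofibroblast replicate 2). Mmp3 fell from 1427 ± 608 to 229 ± 184 and Adm, the vasodilator adrenomedullin, from 665 ± 223 to 24.7 ± 16 (adjusted p = 1.56e-05).

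Of 16 imprinted growth genes 3 fell, and the call of the list was lost without fibroblast replicate 3 and with an estimated correlation. Mest went from 748 ± 521 to 24.4 ± 5.71 (adjusted p = 5.44e-05), Igf2 from 521 ± 54.9 to 128 ± 44.9 (adjusted p = 0.00713) and Cdkn1c from 100.2 ± 27.7 to 13.4 ± 5.17 (adjusted p = 0.00303). The levels of Mest, Igf2 and Cdkn1c in myofibroblast culture were within background, as was that of Cdkn1c in fibroblast culture.

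Contractile and collagen genes, which name the myofibroblast, mostly did not pass. Acta2 was at 2046 ± 1236 in fibroblast and 2983 ± 69.1 in myofibroblast culture (log2 0.81, adjusted p = 0.716) and Tagln at 1803 ± 1236 and 2560 ± 392 (adjusted p = 0.743). Of 22 contractile genes 0 passed. Col1a1 was at 6225 ± 729 and 6054 ± 683 (adjusted p = 0.992), Col3a1 at 465 ± 320 and 959 ± 177 (adjusted p = 0.36) and Fn1 at 5115 ± 416 and 5497 ± 462 (adjusted p = 0.969). Of 11 collagens 1 rose and 0 fell, the same adjusted over the list alone. It was Col11a1, a fibrillar collagen of cartilage, at 279 ± 135 and 671 ± 104 (adjusted p = 0.0465), which did not pass without fibroblast replicates 1 (0.158) or 2 (0.12) or without myofibroblast replicates 1 (0.153), 2 (0.0686) or 3 (0.185).

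Few keratocyte markers passed. Aldh3a1 was at 1565 ± 1886 and 15.4 ± 25 (adjusted p = 0.035), at the floor on 2 myofibroblast arrays, and did not pass without fibroblast replicates 1 (0.0954) or 3 (0.128) or without myofibroblast replicates 1 (0.12), 2 (0.117) or 3 (0.0518). Kera was at 44.7 ± 41.5 and 8.96 ± 4.46 (adjusted p = 0.878), within background. Lum was at 2262 ± 540 and 2446 ± 608 (adjusted p = 0.993) and Dcn at 5136 ± 438 and 4714 ± 418 (adjusted p = 0.916). Of 10 keratocyte markers 1 fell and 9 did not pass, the same adjusted over the list alone.

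Across all probe sets 111 differed, 30 higher and 81 lower in myofibroblast culture (96 by 2-fold or more, 27 and 69), and 63 and 95 after quantile normalization or 55 and 85 after centring. Of 11 lists called, the fall of complement and host defence genes (adjusted p = 8.66e-06) also passed with an estimated correlation (0.0126). The rises of TGF-beta responsive genes (0.00066, adjusted p = 0.526 with an estimated correlation) and collagens (0.000861, adjusted p = 0.0905 with an estimated correlation) did not, nor did the falls of macrophage markers (0.00066, 1 of 24 lower, 9 adjusted over the list alone; adjusted p = 0.526 with an estimated correlation) and keratocyte markers (0.00931, adjusted p = 0.526 with an estimated correlation). The fall of cell cycle genes (6.79e-05, 1 of 37 lower; adjusted p = 0.526 with an estimated correlation) was at 0.0795 without fibroblast replicate 2. The rise of immediate early genes (0.00404, 0 of 18 past the threshold; adjusted p = 0.39 with an estimated correlation) and the fall of imprinted genes (0.00487, adjusted p = 0.539 with an estimated correlation) were each at 0.17 without fibroblast replicate 3. The rise of glycosaminoglycan synthesis genes (0.0291, 0 of 17 past the threshold; adjusted p = 0.526 with an estimated correlation) ended without fibroblast replicates 1 (0.0515) or 2 (0.124) or myofibroblast replicate 1 (0.0634). The fall of interferon-stimulated genes (0.0291, 1 of 23 lower; adjusted p = 0.539 with an estimated correlation) ended without fibroblast replicates 2 (0.0574) or 3 (0.315) or myofibroblast replicate 1 (0.0934). The fall of antioxidant genes (0.0354, 1 of 32 lower; adjusted p = 0.674 with an estimated correlation) ended without fibroblast replicates 1 (0.105) or 3 (0.147) or myofibroblast replicate 2 (0.235).

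Replicate numbers paired these arrays, which the main test did not use. With the number as a block in the fit of all groups 173 probe sets differed, 56 higher and 117 lower, including the 111. That block was shared with groups whose numbers did not pair, so 173 is not the result of a paired test. A paired fit of the myofibroblast and fibroblast arrays alone was not run. With no block the count was 61 without myofibroblast replicate 3 and 16 with only the 2 groups in the fit. In that fit of 2 groups Crabp2 (adjusted p = 0.129), Ccn4 (0.0893), Ccl2 (0.209), Cxcl5 (0.184), Saa3 (0.156), Mmp3 (0.279) and Igf2 (0.0943) did not pass. The number of lists was 7 without fibroblast replicate 3.

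Myofibroblast culture compared with keratocyte culture gives the joint effect of the change of serum and of TGF-beta1. Apoe, Apod, Saa3 and chemokine genes were among the falls. Apoe, an apolipoprotein made by macrophages among other cells, went from 3238 ± 391 to 106 ± 92.7 (adjusted p = 0.00171) and Apod, an apolipoprotein of quiescent fibroblasts, from 3361 ± 1970 to 74.9 ± 51.5. Saa3 fell from 5205 ± 133 to 345 ± 173 (adjusted p = 4.36e-06), Ccl2 from 843 ± 158 to 97.2 ± 42.9, Ccl9, a chemokine of macrophages, from 645 ± 55.2 to 32.3 ± 19.7, and Lcn2 from 905 ± 157 to 37.9 ± 31.1. Of 14 complement and host defence genes 6 fell and 0 rose, 7 adjusted over the list alone. Mmp12, the macrophage elastase, fell from 1574 ± 409 to 125 ± 18.2 and Mmp3 from 2611 ± 256 to 229 ± 184. Of 24 macrophage markers 11 fell and 0 rose, 12 adjusted over the list alone, among them Cd68, a lysosomal protein, from 389 ± 36.2 to 67.9 ± 7.65 and Tyrobp from 199 ± 53.4 to 25.1 ± 6.25.

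Some keratocyte markers fell. Ptgds went from 1140 ± 74.8 to 232 ± 52.4 (adjusted p = 0.000349) and Tkt from 1062 ± 450 to 345 ± 34.8 (adjusted p = 0.00137). Aldh3a1 fell from 2076 ± 1839 to 15.4 ± 25 (adjusted p = 0.00729, 0.0503 with only the 2 groups in the fit). Kera was at 165 ± 150 and 8.96 ± 4.46 (adjusted p = 0.0732, 0.00319 without keratocyte replicate 2). Lum was at 2309 ± 1086 and 2446 ± 608 (adjusted p = 0.821) and Dcn at 5285 ± 428 and 4714 ± 418 (adjusted p = 0.461). Of 10 keratocyte markers 3 fell and 7 did adjusted over the list alone. Of 7 pigment cell markers 6 fell, the same adjusted over the list alone, with Tyrp1, a melanin enzyme, falling from 401 ± 85.8 to 13.8 ± 13.4.

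Metabolic genes fell in part. Of 16 glycolysis genes 7 fell and 1 rose, 9 and 2 adjusted over the list alone, with Pfkl, a phosphofructokinase, falling from 619 ± 42.1 to 241 ± 61.1 and Tpi1, triosephosphate isomerase, from 2275 ± 218 to 1155 ± 212. Of 14 cholesterol synthesis genes 3 fell and 8 did adjusted over the list alone, with Sqle, squalene epoxidase, falling from 557 ± 62.8 to 229 ± 71. Of 32 antioxidant and detoxification genes 8 fell, and 11 fell and 1 rose adjusted over the list alone, with Gsta4, a glutathione transferase, falling from 668 ± 127 to 17.2 ± 19 and Mt2, a metallothionein, from 3529 ± 316 to 1122 ± 486. Of 16 imprinted growth genes 4 fell, and of 12 genes of the insulin-like growth factor system 3, and neither list passed (adjusted p = 0.126 and 0.684). Igf2 fell from 768 ± 333 to 128 ± 44.9, Mest from 207 ± 49.7 to 24.4 ± 5.71 and Cdkn1c from 172 ± 71.7 to 13.4 ± 5.17.

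Genes that rose were fewer. Anxa8 went from 54.6 ± 11.3 to 443 ± 69.5 (adjusted p = 4.36e-06), Cdkn2b from 28.1 ± 2.02 to 238 ± 65.2, Il11, a cytokine induced by TGF-beta, from 61.6 ± 7.77 to 197 ± 92.9 (adjusted p = 0.0105) and Ier3, an early response gene, from 964 ± 204 to 2107 ± 343. Acta2 was at 3193 ± 142 and 2983 ± 69.1 (adjusted p = 0.934), Tagln at 3527 ± 466 and 2560 ± 392 (adjusted p = 0.649), Col3a1 at 1185 ± 87.9 and 959 ± 177 (adjusted p = 0.777) and Fn1 at 4358 ± 235 and 5497 ± 462 (adjusted p = 0.263). Of 22 contractile genes 1 fell and 0 rose. Col1a1 was at 4870 ± 230 and 6054 ± 683 (adjusted p = 0.136, 0.0117 after centring).

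Across all probe sets 620 differed, 114 higher and 506 lower in myofibroblast culture (405 by 2-fold or more, 58 and 347), and 274 and 410 after quantile normalization or 275 and 373 after centring, which took the median log2 difference of all probe sets from -0.13 to 0.048. Camera called 12 lists, of which 0 passed with an estimated correlation. They were falls of pigment cell markers (1.72e-06, adjusted p = 0.0978 with an estimated correlation), macrophage markers (7.85e-06, adjusted p = 0.284 with an estimated correlation), keratocyte markers (0.000641, adjusted p = 0.284 with an estimated correlation), complement genes (0.000641, adjusted p = 0.0599 with an estimated correlation), cholesterol synthesis (0.00149, adjusted p = 0.447 with an estimated correlation) and glycolysis (0.00487, adjusted p = 0.284 with an estimated correlation). The rises were collagens (0.00044, 1 of 11 higher and 1 lower, 3 and 1 adjusted over the list alone; adjusted p = 0.0599 with an estimated correlation), skeletal muscle markers (0.00487, 0 of 18 past the threshold; adjusted p = 0.284 with an estimated correlation) and glycosaminoglycan synthesis (0.0172, 0 of 17 past the threshold; adjusted p = 0.447 with an estimated correlation). The rise of endoplasmic reticulum genes (0.0172, 1 of 17 higher; adjusted p = 0.554 with an estimated correlation) ended without keratocyte replicate 2 (0.0859) or myofibroblast replicate 1 (0.106). That of immediate early genes (0.0347, 1 of 18 higher and 1 lower; adjusted p = 0.402 with an estimated correlation) ended without keratocyte replicate 2 (0.0559), myofibroblast replicates 1 (0.123) or 2 (0.108), and after quantile normalization (0.0557) or centring (0.0569). The fall of antioxidant genes (0.0407, adjusted p = 0.74 with an estimated correlation) ended without keratocyte replicate 1 (0.072) or myofibroblast replicate 2 (0.168). Chemokines did not pass (0.0992), but did after quantile normalization (0.0227) and centring (0.0212).

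The number of probe sets was 298 without keratocyte replicate 1, 304 without keratocyte replicate 3 and 411 without myofibroblast replicate 3. With array quality weights 2648 differed.

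**Figure D3:**
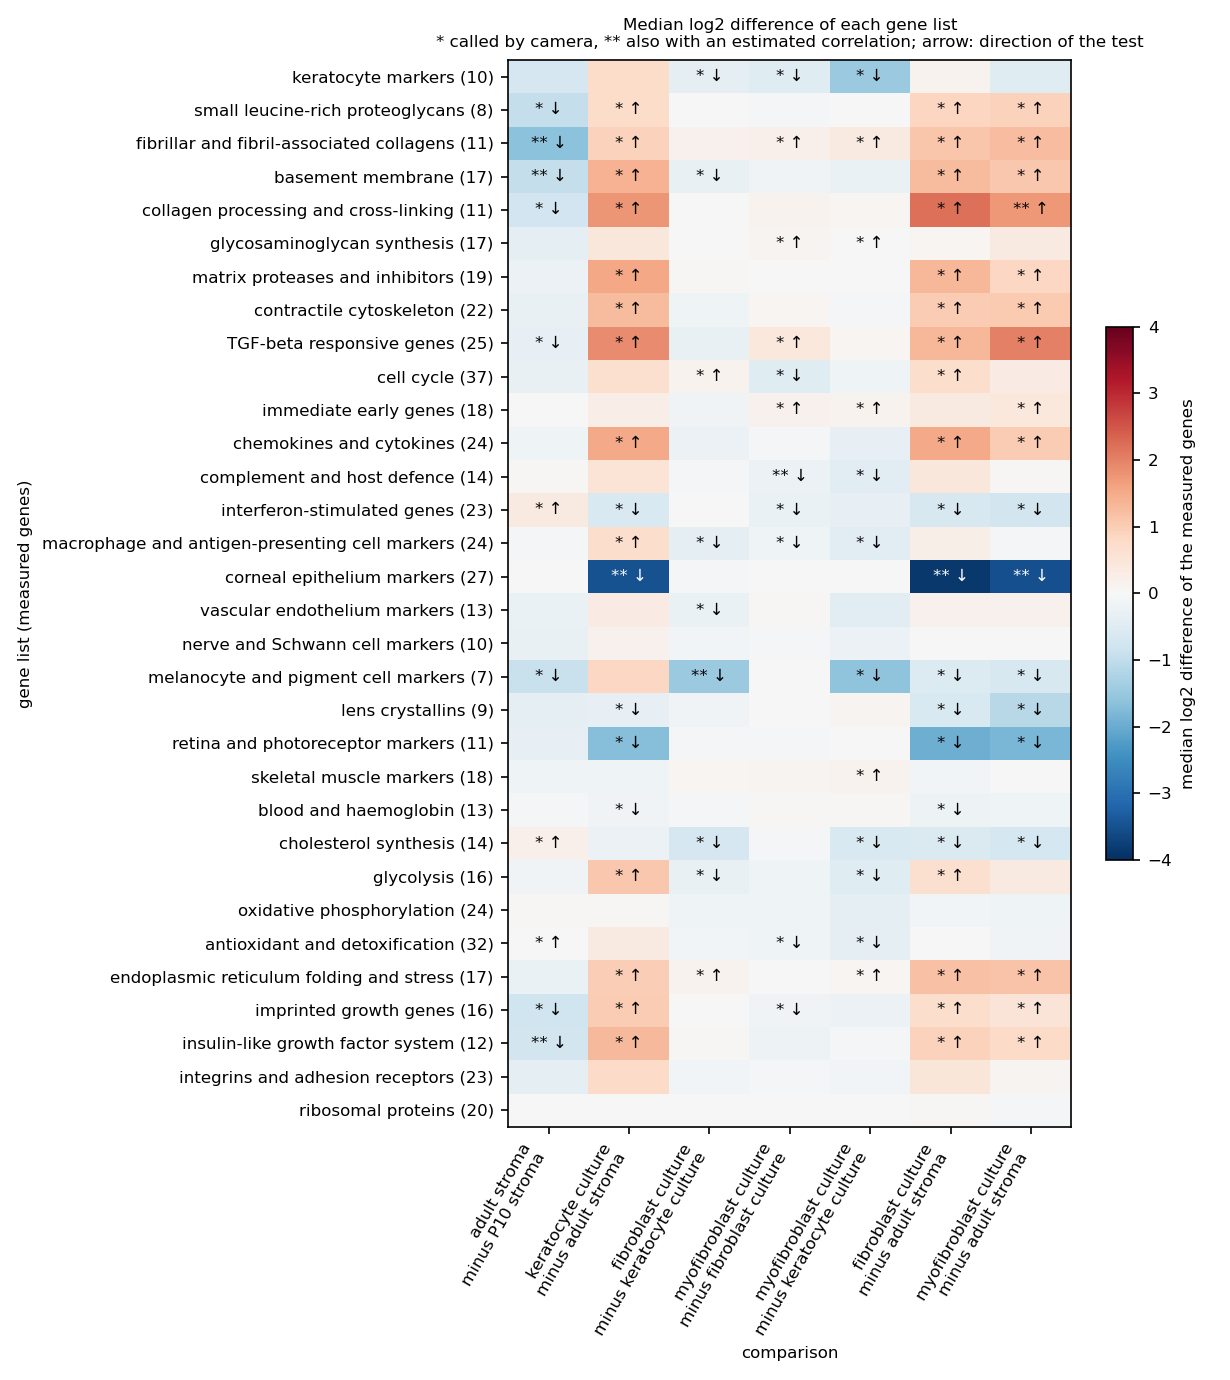
Median log2 difference (colour) of the measured genes of 32 lists in 7 comparisons, with an asterisk where camera called the list, a pair of asterisks where it also passed with an estimated correlation, and an arrow for the direction of the test. Corneal epithelium markers had the largest shifts, with a median of -3.47 in keratocyte culture minus adult stroma.

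The 2 other cultures were also compared with adult stroma, which asks whether the changes of culture are shared. Epithelium markers fell in both, 23 of 27 in fibroblast culture (adjusted p = 2.39e-25, 0.0075 with an estimated correlation) and 24 of 27 in myofibroblast culture (1.88e-22, 0.0117 with an estimated correlation). Of 11 collagen processing genes 8 rose and 1 fell in each (2.4e-05, adjusted p = 0.0516 with an estimated correlation, and 8.98e-06, 0.0358 with an estimated correlation). TGF-beta responsive genes rose, 18 of 25 in fibroblast culture (1.05e-06, adjusted p = 0.151 with an estimated correlation) and 19 of 25 in myofibroblast culture (8.33e-09, adjusted p = 0.113 with an estimated correlation). Cell cycle genes rose in fibroblast culture, 17 of 37 with 2 falling (0.000419, adjusted p = 0.366 with an estimated correlation). In myofibroblast culture 13 rose and 4 fell, and the list did not pass (adjusted p = 0.0563). In all 3189 probe sets differed in fibroblast culture, 1910 higher and 1279 lower, and 3420 in myofibroblast culture, 1814 higher and 1606 lower, with 20 and 18 lists called. In myofibroblast culture the balance turned to 1728 higher and 1840 lower without adult replicate 2, and to 1350 and 1401 without myofibroblast replicate 1. The lists of nerve and Schwann cells, oxidative phosphorylation, integrins and ribosomal proteins were called in 0 of 7 comparisons, with lowest adjusted p of 0.459, 0.0531, 0.256 and 0.289.

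The likeness of each array to adult stroma was measured across probe sets. The correlation with the adult mean was 0.696 ± 0.0099 in keratocyte, 0.685 ± 0.015 in fibroblast and 0.674 ± 0.0063 in myofibroblast culture (SD, n = 3 each), and 0.93 and 0.927 on the P10 arrays. Exact two-sided permutation tests between the cultures gave p = 0.4 for keratocyte against fibroblast, 0.1 for keratocyte against myofibroblast and 0.4 for fibroblast against myofibroblast (0.4, 0.3 and 0.4 after Benjamini-Hochberg adjustment over 3 tests), where 0.1 is the smallest p that 3 arrays against 3 allow, so these tests could not find a difference. Within each replicate number, looked at after the values were seen, the order was keratocyte, fibroblast, myofibroblast (0.689, 0.678 and 0.669 for number 1, 0.707, 0.702 and 0.681 for number 2, and 0.691, 0.675 and 0.672 for number 3). Keratocyte arrays did not meet the rule for pairing with the other cultures, so this order is not a paired test.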

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

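No named gene or list reversed, but the balance of higher and lower probe sets in myofibroblast minus adult turned without adult replicate 2 (1728 and 1840) and without myofibroblast replicate 1 (1350 and 1401). Of 8709 values of 440 gene results under the alternatives 617 fell short of the threshold and 123 newly passed it, and of 2990 values of 143 list results 205 and 42 did. Most losses of genes came with an array left out or a stricter threshold, which leave less to test on or ask more, and 90 of the losses of lists came with an estimated correlation. For the others the cause was not tested. Median-centring and quantile normalization moved no total of probe sets beyond 1.5 times, but raised the number of higher ones beyond it in adult minus P10, fibroblast minus keratocyte, myofibroblast minus fibroblast and myofibroblast minus keratocyte, and that of lower ones in keratocyte minus adult. Signals near background limit what can be seen in weakly expressed genes. Every alternative chosen before the data were examined was run.

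With 1 added to the signals fibroblast minus keratocyte culture gave 83 probe sets. With only the 2 groups in the fit adult minus P10 gave 225, fibroblast minus keratocyte 46 and myofibroblast minus fibroblast 16. With array quality weights adult minus P10 gave 2335, keratocyte minus adult 6366, fibroblast minus keratocyte 360, myofibroblast minus keratocyte 2648 and myofibroblast minus adult 5155. With the Gapdh ratio as a covariate adult minus P10 gave 198, fibroblast minus adult 2023 and myofibroblast minus adult 2038. At an adjusted p below 0.01 the 7 comparisons gave 166, 2103, 34, 47, 297, 2090 and 2218. At 2-fold or more keratocyte minus adult gave 1771, myofibroblast minus keratocyte 405, fibroblast minus adult 1730 and myofibroblast minus adult 1805. With an estimated correlation 3, 1, 1, 1, 0, 1 and 2 lists were called, and fry called 1 in myofibroblast minus fibroblast culture.

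The correlation with adult stroma of keratocyte, fibroblast and myofibroblast cultures was 0.634, 0.625 and 0.614 with 1 added, 0.726, 0.713 and 0.7 with 64 added, 0.801, 0.791 and 0.782 with no filter, and 0.594, 0.583 and 0.572 with a filter at 100.

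The replicate number was added as a block to the fit of all groups. Adult minus P10 then gave 628 probe sets, fibroblast minus keratocyte 214, myofibroblast minus fibroblast 173 and myofibroblast minus keratocyte 1007. Outside myofibroblast minus fibroblast culture the numbers did not meet the rule for pairing at every number, with correlations of deviations of 0.17 and -0.34 in adult minus P10, 0.31, -0.16 and -0.033 in keratocyte minus adult, 0.2, 0.57 and 0.069 in fibroblast minus keratocyte, 0.22, 0.41 and 0.074 in myofibroblast minus keratocyte, 0.21, -0.014 and -0.016 in fibroblast minus adult, and 0.19, 0.067 and 0.058 in myofibroblast minus adult, and not every array went best with its own number. Among named genes of the paired comparison Id2 (adjusted p = 0.00841), Ifi202b (0.0112), Dusp1 (0.0488) and Gsta4 (0.0488) passed only under the block. In the others 13 further gene results passed under it, among them Lum in adult minus P10 (0.0496) and in keratocyte minus adult (0.0142), Aldh3a1 in keratocyte minus adult (0.0185) and Kera in myofibroblast minus keratocyte (0.0159). Myog in keratocyte minus adult (0.0528) and, in fibroblast minus keratocyte, basement membrane (0.0594) and vascular endothelium (0.0745) no longer passed. Newly called lists were keratocyte markers (0.0415) and oxidative phosphorylation (0.0207) in adult minus P10 and skeletal muscle markers (0.0387) in fibroblast minus keratocyte. The block changed no other call of a named gene or a list.

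Leaving out 1 array gave 117 to 495 probe sets in adult minus P10, 2380 to 3359 in keratocyte minus adult, 20 to 144 in fibroblast minus keratocyte, 61 to 151 in myofibroblast minus fibroblast, 298 to 678 in myofibroblast minus keratocyte, 2575 to 3463 in fibroblast minus adult and 2751 to 3568 in myofibroblast minus adult. The lists called were 11 to 16, 15 to 18, 6 to 9, 7 to 11, 10 to 13, 19 to 20 and 17 to 20. The correlations with adult stroma were 0.675 to 0.703, 0.662 to 0.691 and 0.655 to 0.676. Named genes that passed whichever array was left out were 30 of 53, 126 of 133, 10 of 38, 22 of 34 and 50 of 69 in the first 5 comparisons.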

Other observations

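The degradation tests of the epithelial and the Kera patterns, the test of a shared source and the comparison of the pan-leukocyte with the macrophage shift were chosen only after the result was seen. The genes of this and the next paragraph were chosen after their values were seen. Zic1, Nr2f1 and Cdh5 had their highest mean in keratocyte culture. Zic1, a transcription factor of neural crest and brain, was at 405 ± 84 (SD, n = 3) there, 16.2 ± 5.02 (n = 3) in adult and 107 ± 29.9 (n = 2) in P10 stroma, and 59.3 ± 48.7 and 22.3 ± 18.3 (n = 3 each) in fibroblast and myofibroblast cultures. Nr2f1, a nuclear receptor of eye and neural crest development, was at 371 ± 106, 3.84 ± 2.01, 41.8 ± 18.3, 42.5 ± 32.6 and 20.4 ± 4.4 in the same order, and Cdh5, a cadherin of endothelium, at 317 ± 63.6, 4.13 ± 5.42, 67.2 ± 18.3, 47.7 ± 43 and 5.25 ± 4.14. Pax6, the eye field factor also active in corneal epithelium, was at 242 ± 61.2 in keratocyte culture and 957.7 ± 154 in adult stroma.

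Fibroblast replicate 3 differed from the other fibroblast arrays in several of these genes. On replicates 1, 2 and 3 Zic1 was at 87.79, 87 and 3.076, Pax6 at 59.19, 57.58 and 1.86, Cdh5 at 85.53, 56.66 and 1, and Mest at 380.9, 518.1 and 1344. Myofibroblast replicate 3 was likewise the lowest of its group for Zic1 (3.287), Pax6 (3.247) and Cdh5 (1). Mest, at 27.23 there, lay between the other myofibroblast arrays. All of these myofibroblast levels are within background. Pigment genes differed between the P10 arrays, with Dct at 887.9 and 1916 and Tyrp1 at 167.3 and 719. Mt2, a metallothionein, was at 2689 ± 333 in adult stroma and 1111 ± 490 and 1122 ± 486 in fibroblast and myofibroblast cultures.

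Macrophage markers were lower in myofibroblast than in keratocyte culture. The macrophage list shares 0 genes with the other fixed lists and 6 with 19 pan-leukocyte genes. The median log2 difference of the pan-leukocyte genes was -0.179 (95% interval -0.427 to -0.0576), with 3 past the threshold. Intervals in this and the next paragraph come from 2000 resamplings of genes, so they do not measure the spread between arrays. In keratocyte culture 8 of these 19 genes were below 137.7, within background, and 16 below the highest background value of 256.8. Many of them thus had little room to fall. The macrophage list kept its call by camera after quantile normalization (adjusted p = 1.12e-06). As deposited, its call was lost with an estimated correlation (adjusted p = 0.284). Camera sets the genes of a list against other genes, so a shift common to an array largely cancels. The kept call therefore does not decide on array scaling. The bound set beforehand for the pan-leukocyte genes, a median above -0.25 with an interval excluding -0.5, was met, but it does not decide. It was set beyond the median of the macrophage list itself (-0.428). The interval of the difference between these medians held 0 (difference 0.249, 95% interval -0.163 to 1.37). For it the lists were resampled separately although they share 6 genes, so this interval does not decide either. Blood-derived cells and a change within stromal cells cannot be told apart for these genes.

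Epithelial markers were higher in dissected stroma than in keratocyte culture. Of 14 epithelial adhesion genes, 8 of them also on the epithelium list, 14 were lower in culture, with a median log2 difference of -3.95 (95% interval -5.86 to -3.02). Since 10 of the 14 were within background in culture and 1 in adult stroma, the direction is measured but the size depends on the added 16. Degradation confined to the adult arrays is argued against, since the epithelium list was also higher in P10 stroma than in keratocyte culture. There the median was 3.63 (2.48 to 4.48), with 24 of 27 genes higher. The Actb 3'/5' ratio of the P10 arrays (1.466 and 1.44) was itself above that of every culture array (1.196 or less). Degradation shared by the tissue arrays is therefore not excluded by this test. The titles of the tissue arrays name cornea. Lens and retina markers also had higher median log2 levels in adult stroma (8.40 and 7.34) than in keratocyte culture (6.86 and 5.34). These values go with cells from outside the stroma in the dissected tissue, but do not settle the epithelial genes. Epithelial cells in the dissected tissue and a loss of these genes by the cells in culture cannot be told apart by the adhesion genes. Tissue and culture differ in both, and the adhesion genes fall either way.

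Kera and Aldh3a1 were lower on keratocyte replicate 2 than on replicates 1 and 3. A swap with fibroblast replicate 2 is argued against, since on the axis from keratocyte (0) to fibroblast (1) cultures over 70 probe sets it lay at 0.213 and fibroblast replicate 2 at 0.82. Degradation is argued against by a 3'/5' ratio of Actb of 1.06, against 1.07 to 1.2 on the other 8 culture arrays. The deviations of the culture arrays numbered 2 correlated at 0.57, 0.41 and 0.68, the lowest being 0.41, which a shared source of these arrays would give. These are the correlations of the pairing check, over all kept probe sets, so they say nothing of Kera and Aldh3a1 in particular. Looked at after the values were seen, replicate 2 was the lowest array of each culture for Kera, Lum, Ogn, Aldh1a1 and Tkt. For Dcn, Ptgds, Cd34 and Thbd it was not the lowest in every culture. Aldh3a1 was at the floor on myofibroblast replicates 1 and 2. Low replicates 2 add to the spread within groups of the genes they affect. The signal of the added control transcripts was also highest in its group on keratocyte (649), fibroblast (752.7) and myofibroblast (806.7) replicates 2. Shared cells and shared processing of these arrays cannot be told apart. No biological explanation was tested.

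Other ways to split 3 against 3 arrays number 10 with the real one, too few for a share under 0.05. As many probe sets as observed were called in 1 split each, the real one. Every other split mixes arrays of the real groups, so a true difference widens the spread within its groups and lowers its count. The counts of other splits therefore do not show what arrays without a difference would give. The real and the highest other counts were 3221 and 0 in keratocyte minus adult, 142 and 1 in fibroblast minus keratocyte, 111 and 5 in myofibroblast minus fibroblast, 620 and 0 in myofibroblast minus keratocyte, 3189 and 0 in fibroblast minus adult, and 3420 and 0 in myofibroblast minus adult. In myofibroblast minus fibroblast the 3 other splits that part all replicate numbers gave 0.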
